A study of Drosophila melanogaster with 8 samples.

How the data were processed

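HP1a ChIP-seq was carried out in embryos of the wild-type strain Oregon-R at 14 to 16 h of development. Per the labels' protocols, flies were kept in population cages, embryos up to 16 h old were bleached, washed and crosslinked in 1.8% formaldehyde with heptane, and crosslinked chromatin was precleared, incubated with antibody and collected on beads. The age of 14 to 16 h is that of the sample labels. The series has 8 samples: 4 ChIP samples with the antibody wa191, whose target is HP1a, and 4 input samples, with replicate numbers 1 to 4 in each group taken from the titles. Per the labels, each input served as the control of the ChIP sample with the same number.

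The deposited files are 5 lists of regions of significant enrichment, 1 per ChIP sample and 1 for the replicate set as a whole, called the combined set here. Each line gives a sequence, a start, an end and one value. The submitters' processing notes name Bowtie 0.12.7, and the build is FlyBase release 5 per the file headers. The peak caller, its threshold, the read filters, the normalization and the way the combined set was made are not given in the sources used here. The value of each region is the authors' own score, per the file headers a column without a unit. Its scale is not stated, so it was used only to rank, filter and describe regions within a list. The smallest region was 1301 bp wide in every replicate list and 1001 bp wide in the combined set; whether they were called with the same settings is not given in the sources used here. Regions were called per sample, which allows the called sets of the replicates to be compared, but neither reads nor counts were used here, so the depth is unknown and a weak region missing from a list may lie just under its threshold.

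Sequence lengths were taken from the file headers, and between 2 and 10 regions per list that ran past the end of a sequence were clipped to it. Uextra, named in the headers, had no region in any list and was left out. The genome was divided into the 5 large arms (2L, 2R, 3L, 3R, X), chromosome 4, the 6 scaffolds whose names end in Het, and U. A pericentric window was the 2 Mb at the centromere-side end of each arm (the right end of 2L, 3L and X, the left end of 2R and 3R), and a distal window was the 200 kb at the other end. The covered share is the percentage of bases in enriched regions, out of the full sequence length. Assembly gaps and repeats to which reads cannot be placed were not taken out. An uncovered base may therefore be one where no region could be called. A region was placed by its midpoint where regions were counted.

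Covered shares, widths and scores were computed for each replicate and are given as mean ± SD over the 4 ChIP samples. Ratios between parts of the genome were formed within each replicate, and their log2 values were tested with an exact two-sided sign-flip permutation test with Benjamini-Hochberg adjustment. With 4 replicates the smallest p that test can give is 0.13, so it cannot pass 0.05. Overlap between replicates was measured as the Jaccard index of covered bases and as the share of regions overlapped by at least 1 bp, and was compared with 1000 random circular rotations within each sequence. Wilson intervals at 95% for shares of regions cover counting error only. The computations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and the plots Matplotlib 3.10.9. The overlap and coverage code was tested on simulated lists. With 3170 regions on the 5 arms, a made overlap of 61.5% was recovered as 61.5%. This recovery was built in, since the same overlap code had removed other overlapping regions. On separate lists for the arms and chromosome 4, a made ratio of covered shares of 6 was found as 6.00. Of 40 pairs of independent lists on the 5 arms, 0 had a permutation p under 0.05. That p was for the share of regions overlapped. The p-values printed in the results are for the Jaccard index or for combined-set regions found in all 4 replicates, which were not simulated this way. The simulated pairs held regions of equal width placed at random, without the clustering of the deposited regions. They therefore do not show how the rotation test behaves for clustered lists.

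The tests of the main ratios, overlaps, scores and widths, the pericentric and distal windows and the rule for the regions named in the report were fixed before the data were examined. The ratio of X to 2R, rotation within each part of the genome, and the tests that the closing section names as such were chosen after seeing the data. The rule took the 10 highest combined scores on the arms outside the pericentric and distal windows and the 5 highest on chromosome 4 among regions found in all 4 replicates, the 3 widest regions in each of these parts, and the 3 windows of 1 Mb with the highest covered share outside the pericentric windows. The alternatives fixed in advance were the higher-scoring 50% of each list, merging across gaps of up to 1 kb, reciprocal overlap of at least 50%, coverage of at least 50% of a combined region, overlap on the arms alone, the largest deposited end as sequence length, pericentric windows of 1 and 3 Mb, distal windows of 100 and 500 kb, regions per Mb in place of covered bases, and leaving out each replicate in turn. Restricting the results to replicates 1 and 2 or to replicates 3 and 4 was added after seeing the data.

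Results on genes were planned but not computed. They needed gene positions on release 5, whereas the gene table used here gives release 6, and coordinates were not converted between builds. The overlap of regions with genes, 11 gene lists (pericentric, chromosome 4 and Y genes, heat shock and ecdysone genes, Polycomb targets, heterochromatin proteins, ribosomal proteins and markers of neurons, glia, muscle, trachea and epidermis) and distances to start sites were therefore not analysed here, and none of those lists has a result.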

Results

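Chromatin immunoprecipitation followed by sequencing was used to map heterochromatin protein 1a (HP1a) in wild-type Oregon-R Drosophila melanogaster embryos aged 14 to 16 h. HP1a is a chromodomain protein that binds methylated histone H3 and is concentrated in pericentric heterochromatin. The study comprised 4 ChIP samples made with the antibody wa191 and 4 input samples, and each ChIP replicate was called against its own input. No treatment, genotype or stage was contrasted, so the question the design poses is where HP1a was enriched over input and how far the replicates share those places. The lists held 5406, 5127, 4903 and 4260 enriched regions in replicates 1 to 4, a mean of 4924 ± 488 (SD, n = 4). They covered 21.2, 25.4, 20.7 and 19.7 Mb, a mean of 21.7 ± 2.50 Mb (SD, n = 4). The read depth behind each list is unknown, so no interval on a region's own enrichment is given. The labels do not say whether the replicates came from separate embryo collections. The spread between these samples may therefore be technical. A sign-flip permutation p of 0.13 states only that all 4 values had the same sign, and does not measure that spread. The permutation p-values from rotation compare the placement of regions with random placement along the sequence and measure no spread between samples.

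HP1a-enriched regions filled most of the sequence assigned to heterochromatin and little of the chromosome arms. The 6 heterochromatin scaffolds, which hold centromere-side and Y-derived sequence outside the assembled arms, were covered over 65.1% ± 4.85 of their bases (SD, n = 4). Chromosome 4, the small dot chromosome, was covered over 56.9% ± 6.48. The 2 Mb at the centromere-side end of 2L, 2R, 3L, 3R and X were covered over 35.4% ± 2.39. The remainder of these 5 arms, 109 Mb in all, was covered over 5.39% ± 1.09. U, a sequence of joined unplaced scaffolds, was covered over 54.9% ± 10.7.

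**Figure D1:**
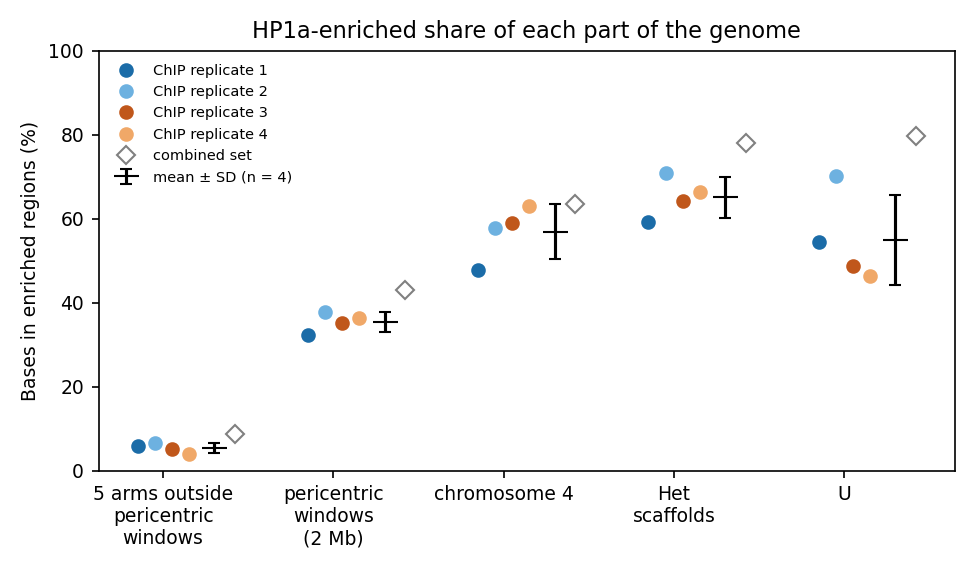
Percentage of bases lying in HP1a-enriched regions (y axis, 0 to 100%) in 5 parts of the genome (x axis). Filled points are the 4 ChIP replicates, bars are mean ± SD, and open diamonds are the authors' combined set. Chromosome 4 and the heterochromatin scaffolds lie between 47.9% and 70.8% in every replicate, and the arms outside the pericentric windows between 4.05% and 6.60%.

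Relative to the arms outside the pericentric windows, the covered share of chromosome 4 was 8.19-fold and 8.75-fold higher in replicates 1 and 2 and 11.6-fold and 15.6-fold higher in replicates 3 and 4, a mean of 11.0 ± 3.38 fold (SD, n = 4). The heterochromatin scaffolds were 12.5 ± 2.80 fold higher than the arms, with values of 10.1 and 10.7 in replicates 1 and 2 and of 12.7 and 16.3 in replicates 3 and 4. The pericentric windows were 6.78 ± 1.57 fold higher than the rest of the arms, with values of 5.51, 5.74, 6.93 and 8.94 in replicates 1 to 4. All 3 differences had the same direction in 4 of 4 replicates. The exact two-sided sign-flip permutation test gave p = 0.13 for each (Benjamini-Hochberg adjusted p = 0.13 over 5 ratios), which is the smallest p that 4 replicates allow. The folds depended on the score threshold, more so in replicates 3 and 4. In the higher-scoring 50% of each list the log2 ratio of chromosome 4 to the arms was 3.70, 3.83, 5.00 and 5.83 in replicates 1 to 4. The full lists gave 3.03, 3.13, 3.54 and 3.96. The mean log2 ratio of chromosome 4 to the arms was 4.59 in the higher-scoring 50%, against 3.42 for the full lists. By number of regions per Mb it was 1.73.

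The covered share of the centromere-side end ranged widely between arms, a difference given here without a test. On 3L the pericentric window was covered over 61.5% ± 4.09 and on 2R over 62.8% ± 4.03 (SD, n = 4), which was 12.9 ± 3.87 fold and 10.6 ± 2.74 fold the share of the rest of the arm. On 2L the window was covered over 34.9% ± 3.27, 7.65 ± 1.90 fold the rest of 2L. On X it was covered over 12.2% ± 1.64, 1.82 ± 0.123 fold the rest of X. On 3R it was covered over 5.37% ± 1.09, against 4.64% ± 1.15 for the rest of 3R, a ratio of 1.17 ± 0.0843 that lay above 1 in 4 of 4 replicates.

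**Figure D2:**
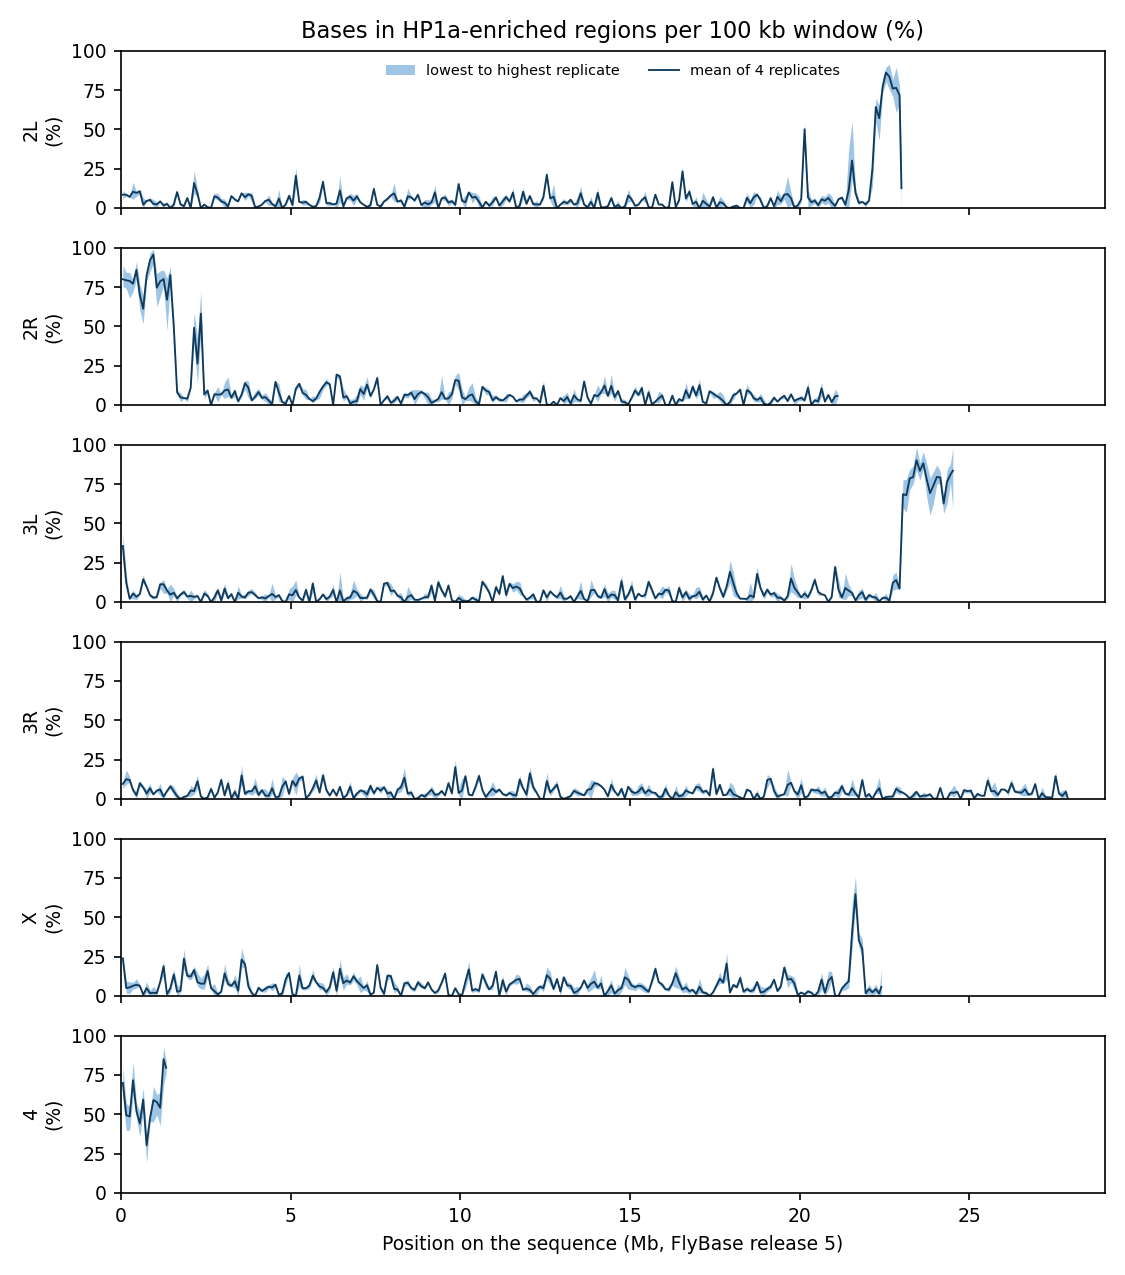
Percentage of bases in HP1a-enriched regions in consecutive 100 kb windows (y axis) along 2L, 2R, 3L, 3R, X and chromosome 4 (x axis, Mb, FlyBase release 5). Lines are the mean of 4 replicates and bands run from the lowest to the highest replicate. Densely covered blocks lie at the right end of 2L and 3L and the left end of 2R, whereas 3R has none and X has one that stops short of its right end.

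Among the heterochromatin scaffolds, 3LHet had the highest covered share, 74.6% ± 4.62 (SD, n = 4). 3RHet was covered over 66.6% ± 5.24, 2LHet over 62.0% ± 6.34 and 2RHet over 61.9% ± 5.01. The smaller XHet, 0.204 Mb long, was covered over 29.8% ± 5.13, with 58.8, 68.6, 29.4 and 19.6 regions per Mb in replicates 1 to 4. YHet, the Y-derived scaffold, was covered over 39.0% ± 7.32, with 28.0% in replicate 1 and 41.7% to 43.3% in the other 3 replicates. On U, replicates 1 and 2 covered 54.4% and 70.2%, and replicates 3 and 4 covered 48.7% and 46.4%. Of all covered bases, the heterochromatin scaffolds held 28.0% ± 2.56, the arms outside the pericentric windows 26.9% ± 3.28, U 25.2% ± 1.97, the pericentric windows 16.4% ± 1.62 and chromosome 4 3.58% ± 0.625.

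Outside the pericentric windows, X was covered over 6.69% ± 0.841, 2R over 6.15% ± 1.23, 3L over 5.03% ± 1.26, 2L over 4.75% ± 1.09 and 3R over 4.64% ± 1.15 (SD, n = 4). The X share was 1.14 and 1.18 times the mean of the 4 autosomal arms in replicates 1 and 2 and 1.51 and 1.49 times in replicates 3 and 4, a mean of 1.33 ± 0.198 fold (4 of 4 replicates, exact sign-flip permutation p = 0.13). The ratio of X to 2R, a comparison added after seeing the data, was 0.973, 1.02, 1.21 and 1.22 in replicates 1 to 4, above 1 in 3 of 4 replicates. This ratio depends on the window edge. The 2R share includes the stretch from 2000001 to 3000000, covered over 20.7%, 23.0%, 14.4% and 14.0% in replicates 1 to 4. A dense X stretch from 21.5 to 21.8 Mb (46.6%) lies inside the excluded pericentric window. The ratio without that 2R stretch was not computed. With pericentric windows of 1 Mb in place of 2 Mb, the mean log2 ratio of X to the autosomal arms was 0.14, against 0.40, and replicate 1 changed sign at -0.02.

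The telomere-side ends were covered more than the arms behind them, though not on every arm. Over the 5 distal windows of 200 kb the covered share was 10.9% ± 3.10 against 5.34% ± 1.07 for the rest of the arms, a ratio of 2.02 ± 0.265 (SD, n = 4; above 1 in 4 of 4 replicates, exact sign-flip permutation p = 0.13). The distal window of 3L was covered over 23.9% ± 6.65, 4.76 ± 0.630 fold the 3L outside its pericentric window. The distal windows of X and 2L were 2.15 ± 0.249 and 1.80 ± 0.210 fold the same part of their arms. On 2L the distal window, at 8.43% ± 1.41, was not denser than the sequence just behind it. The 100 kb windows from 300001 to 600000 each had a higher mean share, and the one from 200001 to 300000 a lower one. The 1.80 fold is therefore not confined to the end of 2L. The highest distal share was that of 3L, and the pooled ratio without 3L was not computed. The distal windows of 2R and 3R were covered over 4.52% ± 3.35 and 3.21% ± 2.22, at ratios of 0.675 ± 0.429 and 0.644 ± 0.322, above 1 in 2 and 1 of 4 replicates. By number of regions per Mb the mean log2 ratio over the 5 arms was 0.18, with replicate 3 at -0.25, against 1.01 by covered bases.

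Regions in heterochromatin were wider than those on the arms. The median width was 2052 ± 20.8 bp on the arms outside the pericentric windows, 3551 ± 597 bp in the pericentric windows, 4736 ± 713 bp on the heterochromatin scaffolds and 4863 ± 1133 bp on chromosome 4 (SD, n = 4). The median width on chromosome 4 was 2.37 ± 0.538 fold that on the arms. With regions merged across gaps of up to 1 kb, the mean log2 width ratio to the arms was 1.98 for chromosome 4, against 1.22, and 1.85 for the heterochromatin scaffolds, against 1.19. The median of the authors' score, which is compared here only within a list, was also higher in heterochromatin in 4 of 4 replicates. The size of this excess is given per list and is not compared between lists, whose highest scores were 3.77, 3.63, 4.88 and 4.87. For the heterochromatin scaffolds the median exceeded that of the arms by 0.0743 and 0.188 in replicates 1 and 2 and by 0.689 and 0.662 in replicates 3 and 4. For chromosome 4 the excess was 0.186 and 0.164 in replicates 1 and 2 and 0.368 and 0.397 in replicates 3 and 4. Each of these width and score differences had an exact sign-flip permutation p of 0.13.

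The replicates shared their regions well beyond chance placement. The Jaccard index of covered bases over the 6 replicate pairs was 0.673 on average and ranged from 0.592 to 0.770. Circular rotation of one list within each sequence gave mean indices of 0.216 to 0.250, and none of 1000 rotations reached the observed index in any pair (one-sided permutation p = 0.001, the smallest that 1000 rotations can give; Benjamini-Hochberg adjusted p = 0.001 over 6 pairs). Replicates 1 and 2 shared 0.755 and replicates 3 and 4 shared 0.770, whereas the 4 pairs across them lay between 0.592 and 0.662. Chromosome 4 was an exception for replicates 1 and 2, which shared 0.802 there, less than the 0.813 and 0.840 of replicate 2 with replicates 3 and 4. Replicates 3 and 4 shared 0.857 on chromosome 4, more than any pair across. The submitters' experiment numbers fall into these same pairs, 1914 and 1916 for replicates 1 and 2 and 2026 and 2027 for replicates 3 and 4. By part of the genome, the index has to be read against rotation within that part, since widely covered parts overlap more by chance. The mean index was 0.580 on the arms outside the pericentric windows against 0.0278 with rotation, 0.762 against 0.348 in the pericentric windows and 0.790 against 0.396 on chromosome 4. It was 0.768 against 0.495 on the heterochromatin scaffolds and 0.612 against 0.371 on U (one-sided permutation p = 0.001 in each part, the smallest that 1000 rotations can give).

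The authors' combined set held 5697 regions over 30.0 Mb, more bases than any single replicate. Of these regions, 2684 were overlapped by at least 1 bp in all 4 replicates (47.1%, 95% Wilson interval 45.8% to 48.4%, counting error only), and 741 in none. Regions found in all 4 replicates made up 62.9% of those on the heterochromatin scaffolds (58.9% to 66.8%), 61.6% on U (58.3% to 64.8%) and 60% on chromosome 4 (50.2% to 69.1%). They made up 48.5% in the pericentric windows (44.3% to 52.7%) and 40.7% on the arms outside them (39.1% to 42.3%). Rotating each replicate list within the part gave mean shares of 53.4% on the heterochromatin scaffolds, 56.2% on U, 37.9% on chromosome 4, 21.4% in the pericentric windows and 0.0374% on the arms outside them. On U the highest rotated share, 63.4%, was above the observed one (one-sided permutation p = 0.002), and in the other 4 parts no rotation reached it (permutation p = 0.001, the smallest possible). The shares of the 5 parts are therefore not comparable without these chance values. The median score in the combined set was 1.33 for regions found in all 4 replicates and 0.63 for those found in none. The combined set was made from the same libraries and is not independent of them. Overlap beyond rotation was therefore largely built in, and these permutation p-values do not measure agreement between replicates.

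**Figure D3:**
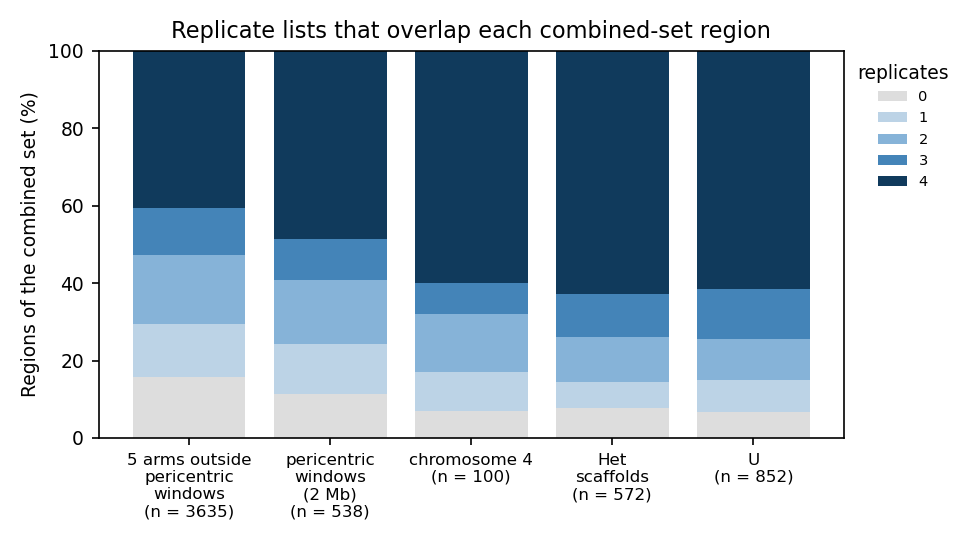
Percentage of combined-set regions (y axis) by the number of replicate lists, 0 to 4, that overlap each region, in 5 parts of the genome (x axis, n is the number of regions). The share found in all 4 replicates runs from 40.7% on the arms outside the pericentric windows to 62.9% on the heterochromatin scaffolds, where rotation gives 0.0374% and 53.4%.

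Among combined-set regions found in all 4 replicates, the highest score on the arms outside the pericentric and distal windows, 3.63, belonged to a region of 7324 bp on 3L from 14747045 to 14754368 (FlyBase release 5), of which each replicate covered at least 98.0%. It was followed by 2784 bp on X from 16109894 to 16112677 with a score of 3.43, 2263 bp on 2R from 18269371 to 18271633 with 3.39 and 2466 bp on X from 19576045 to 19578510 with 3.37. On 3R, 3 of the 10 highest regions lay close together: 8292493 to 8294748 with a score of 3.31, 8333603 to 8335790 with 3.13 and 8330314 to 8332558 with 3.11. The other 3 of the 10 were on X from 2210539 to 2212813 with 3.23, on 3L from 13469301 to 13471629 with 3.23 and on 2R from 19553371 to 19555649 with 3.20. In the combined set these 10 scores were all above the highest on chromosome 4, which was 2.36. In replicates 3 and 4 the order was mixed: the highest of the 5 chromosome 4 regions scored 3.00 and 2.67, above the highest of the 10 arm regions at 2.70 and 2.41, and the lowest of the 5 scored 1.35 and 1.24, below each of the 10. The ranking followed the replicate pairs. Of the 100 highest-scoring regions of a list, 82 and 86 lay on the arms outside the pericentric windows in replicates 1 and 2, against 2 and 3 in replicates 3 and 4. In the combined set, whose scores chose the named regions, 91 lay there and 4 on U. Where overlapped, the arm regions of replicates 1 and 2 had median score percentiles of 84.2 and 84.6 in replicate 3. In replicate 4 these were 73.1 and 73.5. The genes at the named regions were not analysed here.

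The widest regions of the arms outside the pericentric and distal windows lay close together on 2R. They spanned 42408 bp from 2305864 to 2348271, 34839 bp from 2183457 to 2218295 and 33169 bp from 2143287 to 2176455, and were covered over 76.6% ± 20.5, 77.3% ± 12.8 and 76.9% ± 19.2 by the replicates (SD, n = 4). The first of them was covered over 90.5% and 97.8% in replicates 1 and 2 and over 59.3% and 58.9% in replicates 3 and 4. The 1 Mb window of 2R from 2000001 to 3000000 that holds them had the highest covered share of all 107 such windows outside the pericentric windows, 18.0% ± 4.50 against a median of 5.19%. It was followed by 3L from 1 to 1000000 with 9.44% ± 1.59 and 2L from 20000001 to 21000000 with 9.26% ± 1.36.

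On chromosome 4 the regions with the highest combined scores sat at the ends of the sequence. Scores of 2.36 and 2.28 belonged to the regions from 1325543 to 1336533 and from 1338497 to 1349441 at the right end, and 2.18 to the region from 9 to 24923 at the left end. The next were 156749 to 167802 with 2.02 and 521248 to 523435 with 2.02. The widest blocks of chromosome 4 were 49398 bp from 454932 to 504329, 33658 bp from 1050657 to 1084314 and 33592 bp from 1186350 to 1219941, covered by the replicates over 93.2% ± 7.39, 98.2% ± 2.47 and 97.2% ± 2.71 (SD, n = 4).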

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

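Among 86 values examined for a replicate standing apart from the other 3, 4 were singled out, where chance alone gives about 1 in 20, here 4.3. The gap between that replicate and the nearest other was in each case above the 95% critical value of Dixon's test for 4 samples. YHet was covered over 28.0% in replicate 1 and over 41.7% to 43.3% in the others. The distal window of 2L was covered at 1.49-fold the rest of 2L in replicate 2 and at 1.86-fold to 1.93-fold in the others. The chromosome 4 region from 156749 to 167802 was covered over 93.1% in replicate 1 and over 99.5% to 100% in the others. The 2R region from 2183457 to 2218295 was covered over 96.4% in replicate 2 and over 69.2% to 71.9% in the others. No explanation was tested for these values.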

How the results depend on the processing

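The mean of every ratio, score difference and width ratio kept its direction in the alternatives computed, though single replicates did not: replicate 1 for X with pericentric windows of 1 Mb (-0.02) and replicate 3 for the distal windows counted as regions per Mb (-0.25). Of 148 alternatives, 145 were labelled unchanged. For ratios, scores and widths this meant only that the mean kept its direction, whatever its p. For overlaps between replicates it meant a permutation p under 0.05, and restricting the replicates was labelled unchanged without a new test. Covered length had to move by less than 1 SD, and counts by no more than 1.5 times. No ratio could pass 0.05. These labels therefore do not show stability, and the sizes moved as follows. By construction, keeping the higher-scoring 50% of each list lowered the mean number of regions from 4924 to 2462, the mean covered length from 21.7 to 15.8 Mb and the number of combined-set regions found in all 4 replicates from 2684 to 1062. In the same lists the mean log2 ratio to the arms was 4.59 for chromosome 4 (3.42 in the full lists), 4.80 for the heterochromatin scaffolds (3.61), 3.90 for the pericentric windows (2.73) and 1.83 for the distal windows (1.01). Counted as regions per Mb these ratios were 1.73, 1.90, 1.14 and 0.18. A distal window of 100 kb gave 1.49 and one of 500 kb gave 0.57. The X excess of 0.40 was 0.14 with pericentric windows of 1 Mb, which leave part of the covered blocks of 2R and 3L in the arms, and 0.46 with 3 Mb. Reciprocal overlap of at least 50% lowered the mean share of regions overlapped between replicates from 82.5% to 60.4%. Leaving out each replicate in turn gave mean log2 ratios of 3.23 to 3.54 for chromosome 4, 3.48 to 3.71 for the heterochromatin scaffolds, 2.59 to 2.82 for the pericentric windows and 0.34 to 0.47 for X, and folds of 1.94 to 2.15 for the distal windows. Replicates 1 and 2 alone gave mean log2 ratios of 3.08, 3.38, 2.49 and 0.21 for chromosome 4, the heterochromatin scaffolds, the pericentric windows and X, and replicates 3 and 4 alone 3.75, 3.85, 2.98 and 0.59. The distal fold was 2.20 and 1.83 in these pairs, a choice made after seeing the data. Merging across gaps of up to 1 kb moved the mean log2 width ratio to the arms from 1.22 to 1.98 for chromosome 4 and from 1.19 to 1.85 for the heterochromatin scaffolds. The score excess of chromosome 4, averaged over the lists, moved from 0.279 to 0.447. That average pools lists of unlike score range, with excesses of 0.186, 0.164, 0.368 and 0.397 in replicates 1 to 4 before merging. A merged region took the highest score of its parts, which can raise scores where regions lie close together. The sign-flip test cannot pass 0.05 with 4 replicates or fewer, so its p says nothing about stability. No paired analysis was possible because the inputs entered only through the calls of the ChIP sample with the same number, and no region list of an input was used here. The planned results on genes and start sites were not run.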

Other observations

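Of the tests below, those of separate experiments, of strong regions against full lists, of 3R and of dense windows on X were chosen after the results they bear on had been seen, as were the block, window and stretch values and the ranking of regions by part of the genome. Counted inwards from the centromere-side end of the sequence in 100 kb windows covered by at least 50%, the covered block was 0.8 Mb long on 2L and 1.5 Mb on 3L, and 1.3, 1.5, 1.6 and 1.6 Mb long on 2R in replicates 1 to 4. These lengths depend on where the windows start: counted from the other end, the last, partial window of 2L, from 23000001 to 23011544, was covered over 19.8%, 30.6%, 0% and 0% in replicates 1 to 4, so that no block reached the end of 2L, and the window from 22300001 to 22400000 over 42.8% in replicate 1. 3R and X had no such block at their ends. On the 5 arms, beyond the longest block of each arm in any list, 100 kb windows covered by at least 25% in every replicate were found in 5 places. They were 2L from 20.1 to 20.2 Mb (50.1% ± 3.89), 2R from 2.1 to 2.2 Mb (49.1% ± 9.43) and from 2.3 to 2.4 Mb (58.1% ± 11.9), the first 0.1 Mb of 3L (35.5% ± 9.24) and X from 21.5 to 21.8 Mb (46.6% ± 7.79; SD, n = 4). As general background not checked against an annotation here, that part of 2R is known for a large germline piRNA cluster in the cytological region 42AB, and that part of X for the flamenco piRNA locus.

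Coverage of chromosome 4 was uneven along its length. Among its 100 kb windows the share ran from 30.2% ± 8.09 between 700001 and 800000 to 85.1% ± 11.2 between 1200001 and 1300000 (SD, n = 4). The longest stretch with no region in any of the 5 lists was 54928 bp, from 718646 to 773573. In all, 416 kb of chromosome 4 had no region in any list.

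Over all sequences, replicates 1 and 2 shared more with each other, and replicates 3 and 4 with each other, than across these pairs, with a mean Jaccard index 0.134 higher within than across. On chromosome 4 this held for replicates 3 and 4, but replicates 1 and 2 shared less than replicate 2 did with replicates 3 and 4. Of the 100 highest-scoring regions, 87 and 84 lay on U in replicates 3 and 4, against 11 and 9 in replicates 1 and 2. Lists of different length do not account for the closer sharing within pairs. Replicates 1 and 3 covered 21.2 and 20.7 Mb and shared 0.635, whereas replicates 1 and 2 covered 21.2 and 25.4 Mb and shared 0.755. With all lists cut by score to the same covered length the difference was 0.136. That value decides nothing by itself, since a cut by score can keep unlike parts of the genome in the pairs, as the higher-scoring 50% did. The 82 and 86 arm regions among the 100 highest scores of replicates 1 and 2 were not missing from replicates 3 and 4, where at least 97.6% of them were overlapped; other arm regions were not traced. Weak regions near the calling threshold stay open: the 0.137 found in the higher-scoring 50% of each list decides nothing, since 41.2% and 44.3% of that part lay on the arms in replicates 1 and 2 and 21.0% and 14.8% in replicates 3 and 4, and the share of strong regions covered by the full list of another replicate was 0.0722 higher within pairs (0.0917 for all regions), just above the bound of 0.07 set in advance and with ranges that overlapped (0.869 to 0.973 within, 0.759 to 0.946 across). The experiment numbers follow the same pairs, so separate experiments are a candidate source, but the labels give no day or batch, and with 4 libraries this cannot be told apart from chance differences (within minus across, 0.134); no biological explanation was tested.

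The assembled 3R had no covered block at its centromere-side end, unlike 2L, 2R and 3L. Outside the pericentric windows 3R had the lowest mean share of the 5 arms, at least 0.951 times that of 2L and 0.708 to 0.790 times that of 2R. Fewer calls on all of 3R do not account for the missing block, since its pericentric window had only 0.0643 to 0.105 times the share of that of 2R. The scaffold 3RHet was covered over 66.6%, within the range of 2LHet, 2RHet and 3LHet. An assembled arm ending before its heterochromatin would allow this share, but the share cannot decide it. The arms of those other scaffolds do have a block, and XHet was covered over 29.8% although X has no block at its end. Whether the border of HP1a differs between chromosomes was not tested.

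X was covered more than the mean of the autosomal arms in 4 of 4 replicates, though not more than 2R in replicate 1. That 2R share includes the dense window from 2000001 to 3000000, whereas the X stretch from 21.5 to 21.8 Mb lies in its excluded pericentric window. A few dense windows on X do not account for the excess over the autosomal mean. The median 1 Mb window of X was at least 1.15 times that of the autosomal arms in every replicate. The ratio was at least 1.25 in the higher-scoring 50% of each list, so the excess was not confined to low-scoring regions. How the score relates to the calling threshold is not stated. Weak regions near that threshold are therefore not excluded as a source. The depth of X in the input libraries was not analysed here, and no biological explanation was tested.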
